A study of Homo sapiens with 12 samples.

How the data were processed

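RNA of 12 libraries was sequenced, 3 for each of 4 groups: SW480 and HCT116 cells with a control vector (NC) or with USP51 overexpressed, per the labels. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared for a BGISEQ sequencer. Per the submitters' processing notes, TopHat, DESeq 1.32.0 and the genome build hg38 are named. The role of each tool, the counting tool and whether counting used strand are not given in the sources used here.

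The deposited table has 84345 rows of RefSeq transcripts (44726 curated and 39619 predicted, by the prefix of the identifier) with 17818 NCBI gene identifiers. It holds 3 units per group as the authors' means. The deposited values are estimated counts, which need not be whole and are not divided by depth, TPM values, scaled by the authors so that every column has the same total, and FPKM values scaled by the authors to transcript length and depth, per the file headers. Single-library columns exist under codes that match no label, and group membership was not to be inferred from column order or values, so those 36 columns were not used in any result. On a first look at the table, each mean equalled the average of 1 set of 3 of these columns. That match would identify the groups, but it rests on values and was not used. The means are named by cell line with a letter C or E, which the labels do not define. C was read as control and E as USP51 overexpression, and every direction between these groups rests on that reading. USP51 was higher in the E mean of each line.

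The use of means decides what can be said. No n, standard deviation or p-value is given, replicates were not compared with each other, and the tests planned before the data were examined (edgeR quasi-likelihood tests, tests of gene lists with camera, and an interaction test between lines) were left out, not impossible. In their place, transcripts were summed per gene, and log2((TPM with USP51 + 1) / (control TPM + 1)) was computed for genes with at least 1 TPM in at least 1 of the 2 groups compared. This scale understates differences of genes with low values. Genes with a ratio of at least 2-fold were counted, a rule of size and not a test. Gene symbols and coordinates came from the RefSeq table of GRCh38.p14, in which 17672 of the 17818 identifiers had a symbol.

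Ratios of counts per total count are given with 95% exact Clopper-Pearson intervals, conditional on the sum, on the means rounded to whole numbers. Against a mean that rounded to 0 counts a fold is computed at a floor of 3 counts, and the bound of the exact interval can be less extreme. Mean total counts were 15506686 to 15920306 per group, and intervals and floors cover counting error only, since PCR copies are not independent molecules.

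The 32 gene lists, with 571 genes of which 548 were found in the table, were fixed before the data were examined. A list with at least 5 measured members was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size drawn from the same bins of abundance (20 bins). A percentile of at most 2.5 or at least 97.5 was called outside the range of random lists. Members of a list can be co-regulated, unlike random genes, so lists can fall outside more often than the 1.35 of 27 that chance alone would give. In SW480 12 of 27 lists fell outside, and in HCT116 11 of 27. Whether co-regulation or a response to USP51 makes up the excess was not tested. The percentile describes these means and is not a test of the treatment.

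Genes were named by a rule fixed at the same time and adapted to means: USP51, the 10 largest log2 ratios in each direction with at least 1 TPM in the higher group, up to 4 members of each list outside the range of random lists, the 5 genes of each direction with the largest smaller ratio in both lines, the 5 of each sign that differed most between the lines, and HIF1A, VEGFA, CA9, CD44, PROM1, LGR5, ABCB1, ABCG2, USP22 and USP27X. For the control groups the higher group needed 10 TPM, and 5 genes per direction were taken. The parts of the rule that need replicates (adjusted p, no overlap between libraries) were dropped. The size rule of 2-fold, the percentile limits, the ranking of list members by size and the alternatives of TMM scaling, CPM without factors, FPKM, curated transcripts, 20 counts, 1.5-fold and matching on length were chosen after the values had been looked at. The alternative of curated transcripts summed the deposited values of those transcripts only. It dropped what was assigned to predicted transcripts of the same gene, and reads were not assigned anew. LGR5 was below 1 TPM in all 4 groups. ACTA2, COL1A1, HEG1, HLA-DRB1, MIA and TNNC1, which the rule does not take, were named after their values had been seen. Some genes that the rule takes are not reported here.

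The alternatives fixed beforehand that means allow were RLE and upper-quartile scaling factors from edgeR 4.0.16 (R 4.3.3) applied to the mean counts (which gives CPM in place of TPM, with the same 1 added, so that the unit changes with the scaling), a pseudocount of 0.1, no filter, and a mean of at least 1 CPM. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data, with Poisson counts drawn from the control means at the depth of 1 library. In the simulated values 12183 genes of SW480 and 12279 genes of HCT116 passed the filter of 1 TPM. The 2-fold rule recovered 89.4% of 66 genes changed 2.5-fold and 98.5% of 66 changed 4-fold in SW480, and 83.3% and 95.5% in HCT116. Of genes changed 1.5-fold it recovered 0 of 68 in each line. Of 100 random lists with no shift, 3 in SW480 and 5 in HCT116 fell outside the range, and all 100 lists shifted by 0.3 did. Biological variation was not simulated.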

Results

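Messenger RNA was profiled in SW480 and HCT116, human colorectal cancer cell lines, each carrying either a control vector (NC) or an overexpression construct for USP51. USP51 is a ubiquitin-specific protease, an enzyme that removes ubiquitin from other proteins. The labels describe 12 libraries in 4 groups of 3, made from total RNA of cells grown in serum-containing DMEM and sequenced on a BGISEQ instrument. Only the authors' mean of each group was used here, because the codes of the single-library columns match no label. No replicate spread, standard deviation or p-value accompanies any value, and every difference is between 2 authors' means. The means summed to 15625249 estimated counts in SW480 controls, 15920306 in SW480 with USP51, 15823540 in HCT116 controls and 15506686 in HCT116 with USP51. Intervals in parentheses are 95% exact intervals of a ratio of counts per total count. Each treats a mean as the count of 1 library and covers counting error only, so an interval that excludes 1 does not show that a difference exceeds the spread between replicates.

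The overexpressed gene was examined before any other. USP51 (NCBI gene 158880, chromosome X, 55484616 to 55489848, GRCh38) had an authors' mean of 0.513 TPM in SW480 controls and 25.7 TPM in SW480 with USP51. The corresponding counts were 22.3 and 1168, a ratio of 52.1 (34.3 to 83.5). In HCT116 the control mean was 0 counts against 1706 counts and 40.8 TPM with USP51. That is 580-fold higher at a floor of 3 counts in the control mean, and the lower bound of the exact interval was 471. The related deubiquitinase genes USP22 and USP27X differed little. USP22 stood at 70.7 TPM in SW480 controls and 66.4 TPM with USP51, and at 82.6 and 86.2 TPM in HCT116. USP27X stood at 3.25 and 3.29 TPM in SW480 and at 3.03 and 3.38 TPM in HCT116.

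What USP51 overexpression did to the transcriptome was asked in each line separately. In HCT116, genes of the hypoxia response were higher with USP51. Of the 29 measured members of a list of HIF1 and hypoxia targets, 28 lay above their control value, 15 of them by at least 1.5-fold and 5 by at least 2-fold, and none lay 1.5-fold below it. The median log2 ratio of the list was 0.59, a 1.5-fold difference, and exceeded the medians of all 10000 random lists of equally abundant genes. CA9, a cell-surface carbonic anhydrase (NCBI gene 768, chromosome 9, 35673928 to 35681159), was at 2.17 TPM in controls and 6.38 TPM with USP51, a count ratio of 2.89 (1.87 to 4.57). The glucose transporter gene SLC2A3 went with it, at 1.37 and 5.82 TPM (ratio 4.18, 3.07 to 5.80). ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase, was at 8.78 and 22.4 TPM, and ANKRD37 at 3.47 and 10.1 TPM. The most abundant of the 5 members past 2-fold was NDRG1, at 71.9 and 157.0 TPM (ratio 2.14, 2.03 to 2.26). The member below its control value was ADM, at 65.1 and 62.2 TPM. NDRG1 and ADM were picked out after their values were seen. VEGFA, the angiogenic growth factor gene, differed less, at 36.6 and 44.8 TPM (ratio 1.21, 1.11 to 1.31). HIF1A itself, the gene for the oxygen-regulated subunit of HIF1 (chromosome 14, 61695513 to 61748258), was at 85.0 TPM in controls and 84.1 TPM with USP51, a ratio of 0.972 (0.925 to 1.02). A list of HIF and VHL pathway components had a median of 0.04, at percentile 74.7 of random lists.

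**Figure D1:**
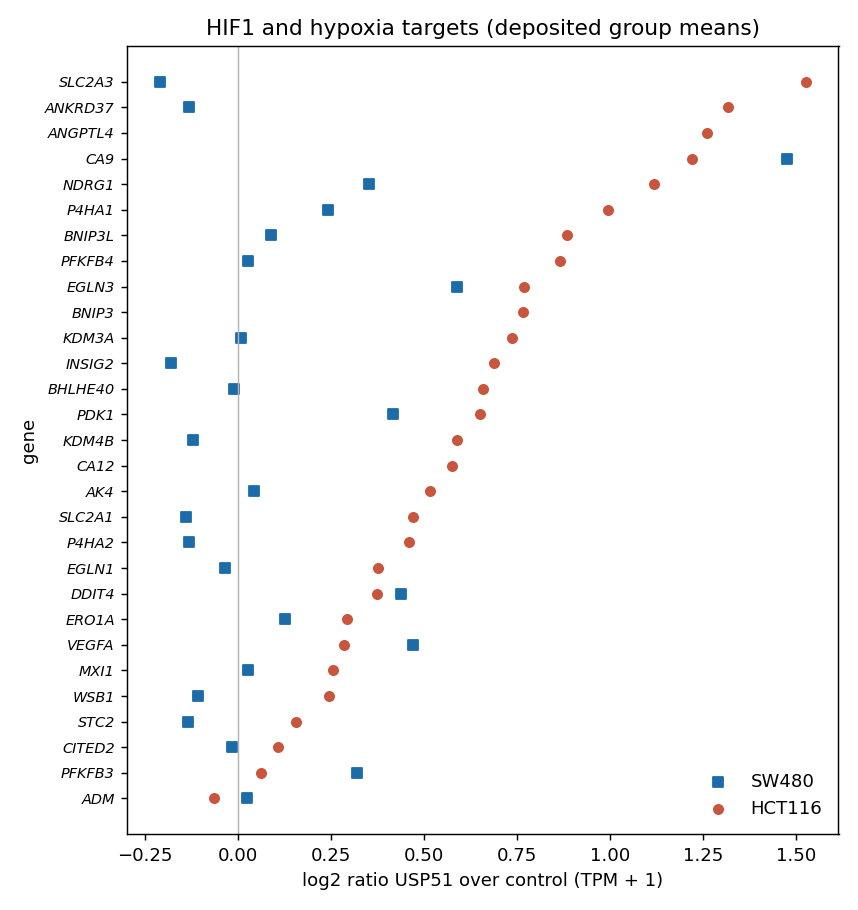
Each point is 1 gene of the HIF1 and hypoxia list, placed by the log2 ratio of the authors' mean TPM with USP51 over control, with 1 added to each mean, for HCT116 (circles) and SW480 (squares). In HCT116, 28 of 29 genes lie above 0, and in SW480 15 of 26, with CA9 farthest to the right among the squares at 1.47. There are no error bars because the means carry no replicate spread.

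Glycolysis enzymes were also higher in HCT116 with USP51. Of 17 enzymes, 16 lay above control and 3 by at least 1.5-fold, with a list median of 0.22. The 3 were ENO2 (36.8 and 71.2 TPM), ALDOC (87.5 and 165.6 TPM) and HK1 (41.4 and 65.5 TPM). WNT target genes had a median of 0.34, with 15 of 17 above control and 4 of them by at least 1.5-fold. Those 4 encode the WNT antagonists NOTUM (10.4 and 21.8 TPM), DKK1 (94.7 and 173.3 TPM) and AXIN2 (17.9 and 32.3 TPM) and the ligand WNT11 (1.87 and 4.53 TPM). Among mesenchymal genes, 10 of 12 lay above control, with a median of 0.31 and 4 past 1.5-fold. Among the 4 were SPARC (0.497 and 3.40 TPM), the matrix-crosslinking enzyme gene LOXL2 (12.6 and 24.6 TPM) and FN1 (6.59 and 10.8 TPM). Of 10 fibroblast markers 2 were measured, and both lay above control in HCT116 by less than 1.5-fold on this scale, COL1A1, also a member of the mesenchymal list, at 9.95 and 15.1 TPM and ACTA2 at 4.60 and 5.51 TPM. YAP targets had a median of 0.33, led by CCN2 (3.01 and 7.66 TPM) and CCN1 (60.5 and 105.9 TPM). Immediate early genes, which answer growth factor signals within minutes, had a median of 0.19 with 18 of 20 above control, and EGR3 (4.24 and 11.2 TPM) and NR4A1 (94.6 and 178.2 TPM) differed most. The medians of these 5 lists lay at percentiles 99.98 to 100 of their random lists.

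Type I interferon genes had a median of 0.17 in HCT116 at percentile 97.7, and were inside the range of random lists under most alternatives. The percentiles were 89.7 to 92.9 in CPM, with or without scaling factors, and 63.6 without a filter on low genes. They were 85.4 under a mean of 1 CPM, 84.7 under 20 counts, 97.2 with FPKM and 97.1 with curated transcripts alone. Other lists were slightly lower in HCT116 with USP51. Genes of ribosome biogenesis and MYC targets had a median of -0.12, with 17 of 20 below control, among them RRS1 (79.2 and 60.9 TPM) and RRP9 (102.1 and 82.0 TPM). DNA replication genes had a median of -0.08 with 20 of 23 below control, among them PCNA (603.4 and 520.5 TPM) and CDT1 (102.6 and 87.0 TPM). NRF2 targets had a median of -0.07 with 14 of 16 below control, and the cystine transporter gene SLC7A11 was at 11.6 and 8.26 TPM. With curated transcripts alone the NRF2 list was inside the range of random lists, at percentile 3.72. No member of these 3 lists differed by 1.5-fold. Lists of colorectal cancer stem cell markers (median -0.02) and of drug efflux and chemoresistance genes (median 0.00) lay inside that range. The stem cell marker CD44 was at 213.7 and 232.0 TPM, PROM1 at 14.6 and 14.3 TPM, and the drug efflux pump genes ABCB1 at 0.917 and 1.19 TPM and ABCG2 at 1.59 and 1.41 TPM.

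Over the whole transcriptome, 32 of 12393 genes were at least 2-fold higher in HCT116 with USP51 and 3 were at least 2-fold lower, both counted on log2(TPM + 1). With curated transcripts alone the split was 43 higher and 13 lower, and with a pseudocount of 0.1 it was 117 and 10. The counting interval excluded a ratio of 1 for 31 of the 32 and for 2 of the 3. Among the higher genes, the largest log2(TPM + 1) ratio after that of USP51 was that of SUSD2, a membrane protein gene, at 5.32 and 22 TPM (count ratio 4.07, 3.42 to 4.86). Next on that scale came SPARC, with a larger count ratio of 6.54 (3.90 to 11.6), and SLC2A3, then the cancer-testis antigen gene MAGEB1 at 2.19 and 7.6 TPM. The perforin gene PRF1 was at 6.21 and 16.8 TPM, PRTN3 at 2.99 and 8.45 TPM, and AFAP1L2 at 0.647 and 2.91 TPM. HBA1 was at 1.89 and 6.23 TPM, on few counts (ratio 3.23, 1.24 to 9.89), and shares its coding sequence with HBA2. Of the genes at least 2-fold lower, PKIB, the gene of a protein kinase A inhibitor, was at 50.3 and 18.3 TPM (ratio 0.391, 0.331 to 0.459). U2AF1, a splicing factor gene, was at 171.1 and 46.1 TPM, but this value is uncertain because the table splits its reads with the near-identical copy U2AF1L5. The third was a locus without a symbol, whose interval included 1. Just short of 2-fold on log2(TPM + 1) were HAS3, a hyaluronan synthase gene (109.1 and 56.1 TPM, ratio 0.504, 0.479 to 0.530), and DPEP1 (18.5 and 8.84 TPM, ratio 0.480, 0.385 to 0.595). The log2 ratio of DPEP1 was 0.00 with curated transcripts alone. VCAN was at 17.6 and 9.73 TPM and HS3ST1 at 20.7 and 12.4 TPM. Applied to simulated counts with Poisson noise alone at the depth of 1 library, the 2-fold rule called 13 of 12081 unchanged genes for HCT116. A mean of 3 libraries has less counting noise than that, so the simulated calls overstate it. Spread between replicates was not simulated.

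In SW480, genes of NF-kB signalling and inflammation were lower with USP51. Of 16 measured list members 15 lay below control, 5 of them by at least 1.5-fold, and the median log2 ratio was -0.47, a 0.722-fold level that lay below all 10000 random lists. The chemokine genes CXCL1 (50.1 and 29.4 TPM, ratio 0.603, 0.519 to 0.70), CXCL8 (17.2 and 10.9 TPM) and CXCL2 (23.8 and 15.4 TPM) were among the 5, as were the cytokine gene LTB (18.3 and 11 TPM) and BIRC3 (7.42 and 4.30 TPM). The member above control was NFKB2, by a log2 ratio of 0.01. CXCL2 and NFKB2 were picked out after their values were seen. Outside the list, the chemokine gene CCL2 was at 117.0 TPM in controls and 52.0 TPM with USP51 (ratio 0.457, 0.393 to 0.530). The acute-phase genes SAA1 (1352 and 623.5 TPM, ratio 0.471, 0.444 to 0.50) and SAA2 (196.1 and 83.4 TPM) were lower as well, although these paralogs are so alike that reads can pass between them.

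Cell division genes were lower in SW480 with USP51, by less than 1.5-fold each. All 20 members of a proliferation list lay below control, with a median of -0.30 that was below all random lists. The topoisomerase gene TOP2A was at 215.3 and 160.1 TPM (ratio 0.767, 0.746 to 0.787), the proliferation marker MKI67 at 103.4 and 77.8 TPM, the mitotic kinesin gene KIF20A at 77.2 and 58.7 TPM, and the mitotic kinase gene PLK1 at 165.9 and 127.5 TPM. DNA replication genes had a median of -0.09 with all 23 below control, inside the range of random lists at percentile 2.61, and the median difference of this list between HCT116 and SW480 was 0.03, at percentile 53.3. DNA damage repair genes had a median of -0.16 with 19 of 20 below control, among them the checkpoint kinase gene ATR (13.0 and 8.81 TPM). YAP targets had a median of -0.22 with 10 of 11 below control, among them AMOTL2 (71.3 and 50.6 TPM) and ANKRD1 (147.0 and 109.9 TPM). Immediate early genes (median -0.14, 15 of 20 below control) included EGR1 at 577.3 and 433.6 TPM and FOSL1 at 317.1 and 235.3 TPM. Heat shock genes had a median of -0.13, with HSPH1 at 217.2 and 174.8 TPM. Type I interferon genes had a median of -0.13, and BST2, the antiviral protein tetherin, was the member past 1.5-fold at 35.7 and 20.5 TPM.

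Few lists were higher in SW480 with USP51, and by small amounts. Cholesterol synthesis genes had a median of 0.13 with 20 of 23 above control, among them DHCR7, the enzyme of the last step to cholesterol (148.2 and 171.9 TPM), and EBP (174.0 and 201.7 TPM). The median was 0.07 for nuclear-encoded oxidative phosphorylation genes, 0.07 for cytosolic ribosomal proteins and 0.06 for fatty acid synthesis genes. The ribosomal protein list was inside the range of random lists in CPM, at percentile 96.8 with or without scaling factors. The hypoxia list had a median of 0.03 in SW480, at percentile 98.8 of random lists whose own median was below 0. With curated transcripts alone it was inside that range, at percentile 96.6. Of its 26 measured members 15 lay above control and 2 by at least 1.5-fold, CA9 at 2.78 and 9.50 TPM (ratio 3.50, 2.42 to 5.19) and the prolyl hydroxylase gene EGLN3 at 8.54 and 13.3 TPM (ratio 1.61, 1.35 to 1.91). VEGFA was at 16.1 and 22.6 TPM (ratio 1.46, 1.29 to 1.65) and HIF1A at 81.5 and 72.9 TPM (ratio 0.922, 0.876 to 0.970). Stem cell markers (median -0.03), drug efflux genes (median -0.06) and WNT targets (median -0.07) lay inside the range of random lists. Within them, ABCB1, the P-glycoprotein efflux pump, was at 7.41 and 12.8 TPM (ratio 1.78, 1.56 to 2.03), CD44 was at 111.2 and 113.0 TPM, and ALCAM was at 3.35 and 1.07 TPM (ratio 0.323). ALCAM was picked out after its value was seen.

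**Figure D2:**
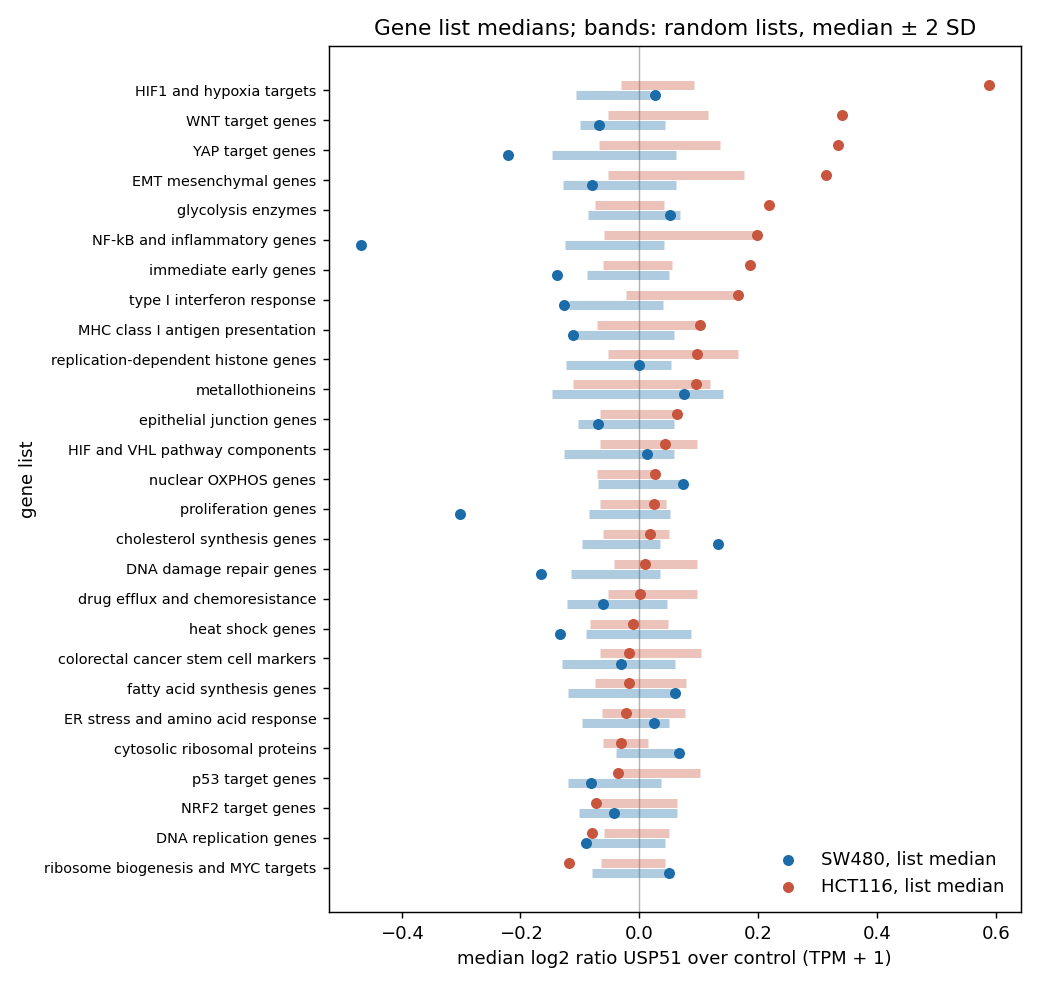
Points give the median log2 ratio of USP51 over control (authors' mean TPM with 1 added) of each gene list with at least 5 measured members, for SW480 and HCT116. Each band spans 2 SD of random-list medians around their median and is not a replicate error. The hypoxia list lies at 0.59 in HCT116 and 0.03 in SW480, and the inflammatory list at -0.47 in SW480.

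In SW480, 9 of 12175 genes were at least 2-fold higher with USP51 and 15 at least 2-fold lower, and the counting interval excluded 1 for 7 and 12 of them. In CPM in place of TPM the split was 11 higher and 12 lower, both without scaling factors and with upper-quartile factors. The same rule called 17 of 11983 unchanged genes in simulated SW480 counts with Poisson noise alone at the depth of 1 library, beside the 24 calls in the data. These 2 numbers are not on equal terms. The data are means of 3 libraries with less counting noise, and the simulation holds no spread between replicates. Higher genes besides USP51 and CA9 included the cyclin gene CCND2 at 7.32 and 17.8 TPM (ratio 2.51, 2.25 to 2.79). CEMP1 was at 0.393 and 2.18 TPM. SLPI, at 19.5 and 38.3 TPM, and AUTS2, at 2.38 and 5.41 TPM, fell just short of 2-fold on log2(TPM + 1). The count ratio of AUTS2 was 2.22 (1.80 to 2.75). Its log2 ratio of 0.92 was 0.25 with curated transcripts alone. Among lower genes, the cancer-testis antigen gene MAGEC2 was at 13.4 and 4.64 TPM (ratio 0.360, 0.279 to 0.461), UBE2L6, the conjugating enzyme of the ISG15 pathway, at 30.0 and 12.8 TPM, and SH3BGRL at 7.24 and 2.76 TPM. COX7B2 was at 4.90 and 1.15 TPM, with an interval of 0.0632 to 0.822. The values of U2AF1 (0.720 and 8.47 TPM), EIF3CL (5.47 and 28.9 TPM) and SULT1A4 (5.26 and 0.107 TPM) are uncertain, since each shares reads with a near-identical copy. The histone genes H4C5, H4C13 and H2AC12 and the receptor gene OR2A42 passed 2-fold on means of fewer than 10 counts, and the intervals of the histone genes included 1.

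The response of each gene was then compared between the lines, as a difference of 2 log2 ratios with no test. Among 11332 genes measured in both, 67 had a log2 ratio at least 1 higher in HCT116 than in SW480 and 7 at least 1 lower. The counts were 36 higher with FPKM, 165 higher and 17 lower with a pseudocount of 0.1, and 18 lower with curated transcripts alone. Trends across genes had opposite signs in the lines. Spearman rho with transcript length was 0.206 in HCT116 and -0.120 in SW480, and with abundance -0.288 and 0.055. Whether these trends shape the split was not tested. The differences were largest upward for SUSD2 (1.64 and 1.31 TPM in SW480), NGFR, HLA-DRA, SPARC and SLC2A3. SLC2A3 was at 449.0 and 388.0 TPM in SW480, far above its level in HCT116. The nerve growth factor receptor gene NGFR was at 161.3 and 86.2 TPM in SW480 and at 6.28 and 14.0 TPM in HCT116. HLA-DRA, an MHC class II gene, was at 3.12 and 1.17 TPM in SW480 and at 2.17 and 5.26 TPM in HCT116. Among the largest differences downward were those of U2AF1, EIF3CL, H4C5 and HAS3, of which U2AF1 and EIF3CL share reads with copies and H4C5 rests on fewer than 10 counts. HAS3 was at 5.47 and 8.65 TPM in SW480, and its log2 ratio there of 0.58 was -0.32 with curated transcripts alone. On log2(TPM + 1), CA9 and USP51 were at least 2-fold higher in both lines, where independent lists would share 0.0127 genes. No gene was 2-fold lower in both on that scale. At 1.5-fold the shared higher genes were CA9, CDKN1C, EGLN3, OLFM1 and USP51, against 0.653 by chance, and USP51 among them is the overexpressed gene itself. SULT1A4 was lower in both, against 0.0609 by chance, but it shares reads with a near-identical copy. The summed counts of gene and copy had log2 ratios of 0.04 in SW480 and -0.06 in HCT116, so a shared change of SULT1A4 is uncertain. At the same 1.5-fold, HEG1, HLA-DRA, HLA-DRB1, MIA, NGFR and TNNC1 were lower in SW480 and higher in HCT116, against 1.05 by chance, and H4C5 and U2AF1 were higher in SW480 and lower in HCT116, against 0.0379. IFI35, an interferon-induced gene, was lower by less, at 19.0 and 12.7 TPM in SW480 and at 16.8 and 11.7 TPM in HCT116. CDKN1C, a cyclin-dependent kinase inhibitor gene, was at 14.2 and 22.3 TPM in SW480 and at 8.83 and 14.5 TPM in HCT116. OLFM1 was at 22.1 and 35.4 TPM in SW480 and at 3.0 and 6.91 TPM in HCT116. The inflammatory list, low in SW480, had a median of 0.20 in HCT116, inside the range of random lists at percentile 96.2. That median rests on 12 measured members, 10 above control and 2 below, against 16 measured in SW480. Some were near 1 TPM in HCT116, where this scale understates differences, among them CXCL1 (0.953 and 1.36 TPM) and CXCL2 (0.72 and 1.14 TPM). The median difference between the lines was 0.62 for this list, at percentile 100, with all 12 members above 0. The proliferation list had a median of 0.02 in HCT116, also inside the range of random lists. Across genes, which are not independent replicates, the log2 ratios of the lines had a Spearman rho of -0.0671 and a Pearson r of 0.0222. Both include USP51, which was raised in both lines by the construct and can pull the Pearson r upward. Neither was computed without it.

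**Figure D3:**
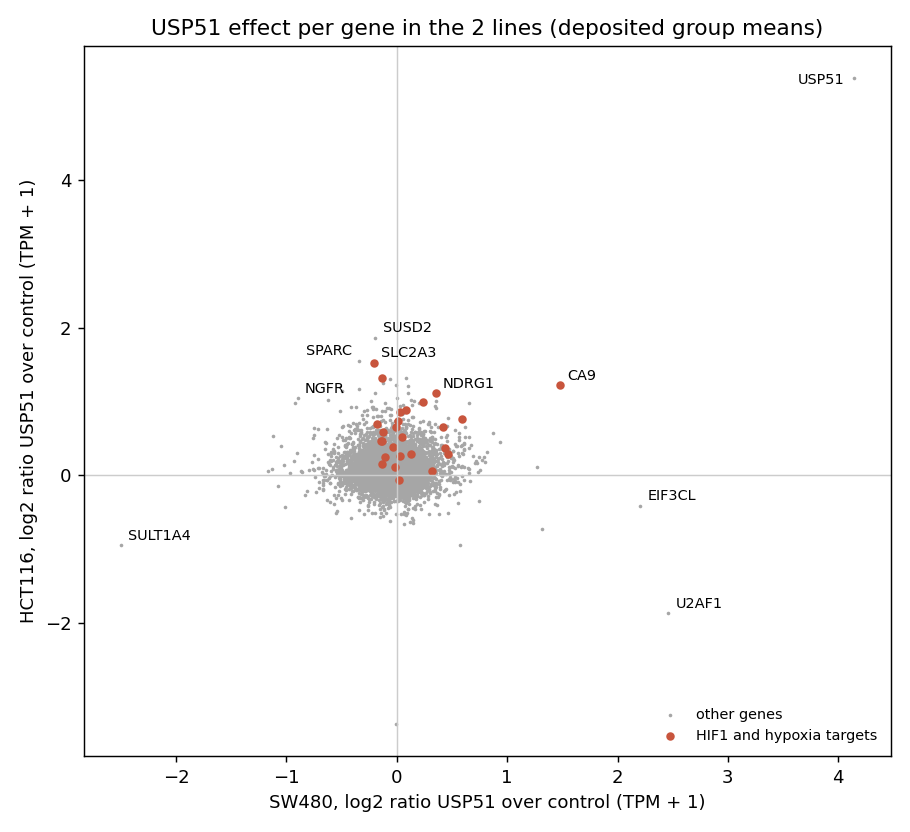
Each point is 1 of 11332 genes measured in both lines, with the log2 ratio of USP51 over control in SW480 on the horizontal axis and in HCT116 on the vertical axis (authors' mean TPM with 1 added). Hypoxia list members are coloured, and CA9, at 1.47 and 1.22, is the member past 2-fold in both lines. U2AF1, EIF3CL and SULT1A4 share reads with near-identical copies.

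The control groups show how far apart the lines were without USP51. SW480 controls were at least 2-fold higher than HCT116 controls for 1741 of 13033 genes and at least 2-fold lower for 1913. SW480 had the basal keratin gene KRT5 at 2871 TPM against 0.163 TPM in HCT116, and the WNT inhibitor gene APCDD1 at 327.3 against 0.0267 TPM. At a floor of 3 counts SAA1 was 1179-fold and CST7 751-fold higher in SW480, and the lower bounds of the exact intervals were 958 and 610. The intermediate filament gene VIM was at 732.5 and 1.58 TPM (count ratio 460, 316 to 698). Its log2 ratio of 8.15 was 1.64 with curated transcripts alone, which leaves out what was assigned to predicted transcripts. HCT116 had the ligand gene KITLG at 379.2 TPM against 0.167 TPM in SW480, S100A14 at 353.0 against 0.533 TPM and the EGF receptor ligand gene EREG at 307.2 against 0.703 TPM. At the same floor GTSF1 was 1091-fold and MAGEB2 930-fold higher in HCT116. The upper bounds of their exact intervals for SW480 over HCT116 were 0.00113 and 0.00132. By list, SW480 controls were higher in inflammatory genes (median 2.5, 15 of 16 higher), WNT targets (2.01), replication-dependent histone genes (1.63) and mesenchymal genes (1.44). They were lower in fatty acid synthesis genes (-0.89), NRF2 targets (-0.63), stem cell markers (-0.57) and p53 targets (-0.55).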

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

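The tests of scaling, of HIF1A and of near-identical copies in this part were chosen after the results had been seen. The differences between the lines below rest on group means and were not tested.

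In some genes and lists the ratio of USP51 over control had opposite directions in the lines. The nerve growth factor receptor gene NGFR had a log2 ratio of -0.90 in SW480 and 1.05 in HCT116, a difference of 1.94. The MHC class II gene HLA-DRA had -0.92 and 0.98, a difference of 1.90. The histone gene H4C5 had 1.3 and -0.72, a difference of -2.04, on means of fewer than 10 counts. U2AF1 had 2.46 and -1.87, a difference of -4.33. The lists taken here were outside the range of random lists in both lines. YAP targets had medians of -0.22 and 0.33 with a median difference of 0.52, immediate early genes -0.14 and 0.19 with 0.33, and type I interferon genes -0.13 and 0.17 with 0.20. For the interferon list the difference lay inside the range of random lists, at percentile 94.6. Some lists inside the range in 1 line also had opposite signs. The medians were -0.08 and 0.31 for mesenchymal genes (difference 0.69), -0.47 and 0.20 for inflammatory genes (0.62) and -0.07 and 0.34 for WNT targets (0.47). They were -0.30 and 0.02 for proliferation genes (0.32), with all 20 differences above 0. These median differences lay at percentile 100. Ribosome biogenesis and MYC targets had medians of 0.05 and -0.12, with a median difference of -0.17 at percentile 0.02.

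The hypoxia targets that were higher in HCT116 with USP51 are a pattern to follow up. The list's median stood 0.551 above the median of all genes (SD of random lists 0.0305), a gap that 1 scaling factor per library cannot make, since it moves all genes by about the same amount. A trend with transcript length or abundance is present across HCT116 genes (Spearman rho of 0.206 and -0.288), yet the list's median was at percentile 100 of random lists matched on both. More HIF1A messenger RNA was not seen, as the upper bound of its count ratio was 1.02. A response to USP51 and culture conditions that differed between the groups, such as cell density, were not tested against each other, and both remain open.

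The inflammatory genes that were lower in SW480 with USP51 had a median that differed from that of all genes by -0.430 (SD of random lists 0.0415), which a single scaling factor per library cannot make either. Matched on length and abundance, the list's median was at percentile 0. These values argue against scaling and against a length or abundance trend as the whole cause. A response to USP51 and a difference between the cultures were not tested against each other and remain open, and replicate spread, which means do not show, was not weighed.

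The ratios of U2AF1, EIF3CL and SULT1A4 are among the largest, and each gene has a near-identical copy. Where reads move between gene and copy, their sum should not differ. For SULT1A4 in SW480 and U2AF1 in HCT116 a change of the gene alone would have moved the log2 ratio of the summed counts to -0.59 and -0.51. The observed sums lay within 0.0396 of 0, consistent with reads assigned differently between the copies. For EIF3CL and U2AF1 in SW480 the copy holds nearly all counts, and a change of the gene alone would have moved the sum by 0.0543 at most, so a change of the gene and a different assignment of reads cannot be told apart.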

How the results depend on the processing

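The alternatives of TMM scaling, CPM without factors, FPKM, curated transcripts, 20 counts, 1.5-fold and matching on length were chosen after seeing the data. No paired analysis was possible because neither the means nor the codes of the single-library columns carry the labels' replicate numbers. Because the single-library columns were not used, DESeq2, limma-voom, the replicate block, leaving out libraries, the joint fit, the adjusted-p threshold, camera with an estimated correlation and fry were not run. No list outside the range of random lists and no named gene past 2-fold changed direction, while HAS3, NSDHL and ABCG2 in SW480 and EIF3CL in HCT116, all short of 2-fold, changed sign with curated transcripts alone. Of the values of gene counts under alternatives, 84 were within 1.5 times the main count and 20 were not. Without a filter the 2-fold counts of each comparison of 2 groups stayed by design. With 1 added, a gene below 1 TPM in both groups cannot reach 2-fold. The 20 include 4 values counted at the lower threshold of 1.5-fold. Of list medians, 383 kept their side of the limit and 35 lost it. Of single-gene log2 ratios, 1688 moved by less than the mean reach of their counting interval on either side, and 102 by more. Ratios whose interval reached 0 or had no upper bound were counted as staying. Changes of the filter alone (none, 1 CPM or 20 counts) cannot move the ratio of a single gene, so those values stayed by design. The hypoxia list in HCT116 ranged from 0.55 to 0.68 and the inflammatory list in SW480 from -0.49 to -0.31. No scaling or unit moved the median of all genes by over 0.1.

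The RLE, upper-quartile and TMM factors were applied to CPM, so the unit changed with the scaling. The USP51 log2 ratio in SW480 was 4.94 in CPM without factors, 4.97 with RLE, 4.94 with upper-quartile and 4.97 with TMM factors, so nearly all of the move came with the unit. It was 5.39 with a pseudocount of 0.1, where its low control value weighs more. With that pseudocount, which lets low genes pass, 29 genes were higher and 45 lower in SW480, 117 and 10 in HCT116, 165 and 17 in the difference between lines, and 1 was lower in both. With FPKM 8 were lower in SW480, 20 higher in HCT116 and 36 higher in the difference. With curated transcripts alone 14 were higher and 24 lower in SW480, 13 lower in HCT116 and 18 lower in the difference, and the share of higher genes in HCT116 was 76.8% in place of 91.4%. The cause was not tested for FPKM and curated transcripts. Under a mean of 1 CPM and under 20 counts, which test other genes, 4 were lower in the difference. At 1.5-fold 65 were higher and 107 lower in SW480, and 243 and 18 in HCT116. Depth limits genes of few counts, such as the histone genes, whose intervals include 1.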

Other observations

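The test in this part was chosen after the result had been seen. Several gene groups outside the main comparisons differed little from control within each line. MHC class I genes had a median log2 ratio of -0.11 in SW480 and 0.10 in HCT116, both inside the range of random lists. Metallothioneins, which bind zinc and copper, had medians of 0.08 and 0.10, and epithelial junction genes -0.07 and 0.06. The ER stress and amino acid response list had medians of 0.03 and -0.02. In SW480 10 of its members lay above control and 8 below, and those farthest above were TRIB3 (44.5 and 65.5 TPM) and ASNS (84.1 and 106.7 TPM). The p53 targets had medians of -0.08 in SW480 and -0.04 in HCT116, the latter outside the range of random lists at percentile 2.32 and inside it under 6 alternatives, at percentiles 2.56 to 4.85. MYC was at 156.3 and 233.2 TPM in SW480 (ratio 1.54, 1.49 to 1.59) and at 196.7 and 181.9 TPM in HCT116. TRIB3, ASNS and MYC were picked out after their values were seen. As untested differences of HCT116 minus SW480, 3 of these lists lay outside the range of random lists. The median difference was -0.17 for ER stress genes (percentile 0.01), 0.21 for epithelial junction genes (percentile 99.8) and 0.19 for MHC class I genes (percentile 97.9), the last of which was inside the range in CPM, with or without scaling factors, at percentiles 97.3 to 97.4.

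Markers of other cell types were few. At least 1 TPM was reached by 2 of 10 fibroblast, 4 of 12 immune and 1 of 8 endothelial markers in SW480, and by 2, 1 and 1 in HCT116. In HCT116 with USP51 the polyamine catabolism gene SAT1 was at 354.3 and 732.9 TPM and the transglutaminase gene TGM2 at 6.28 and 15.4 TPM, genes chosen after their values were seen.

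A hypothesis for the small hypoxia median in SW480 is that its targets were already high in SW480 controls. The 15 list members whose control level was no higher in SW480 than in HCT116 should then have responded in SW480. Their median in SW480 was 0.0274 (SD of random lists 0.0419), against 0.37 in HCT116. The SW480 value lay in the upper part of the range of random lists, at percentile 96.5, but inside it. A high control level is therefore unlikely to be the whole cause. The other 11 members had a median of -0.13 in SW480. The split used the SW480 control mean, which is also the denominator of these ratios. A control mean that lies high by error places a gene among the 11 and lowers its ratio. That median therefore cannot decide whether a high control level has part in the small median.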
